A study of Mus musculus with 36 samples.

How the data were processed

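Kidneys of C57BL/6 mice were profiled on 2-colour Agilent whole-genome oligonucleotide arrays, 1 array per animal. Per the labels, 18 animals were knockouts (KO) for calcineurin beta 1 and 18 were wild types (WT), and each array belonged to a separate biological replicate. The knocked-out gene was taken as Ppp3r1, which encodes the regulatory subunit B type 1 of the calcium-dependent phosphatase calcineurin. Per the labels' protocols, total RNA was extracted with Trizol and labelled with Cy5, and a mouse universal reference RNA, a mixture from cell lines, was labelled with Cy3. No array had the dyes exchanged, so a dye effect of a probe stays in every ratio and cancels only between groups.

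The deposited scanner files were written by Agilent Feature Extraction 10.7.3.1, per the file headers. They hold the mean and local background intensity of each spot in both channels without normalization. They also hold processed intensity values, which were background-subtracted, detrended and dye-normalized with a linear and a lowess step, per the file headers. The deposited log ratio column is the log10 of processed Cy5 over processed Cy3, per the file headers. The deposited spot flags mark spots that were above background, saturated, non-uniform or population outliers. The deposited series matrix holds log10 ratios on the same scale: 44536 of its 44996 lines equalled 1 line of the scanner log ratios on all 36 arrays at 3 digits, and its column medians ran from −0.0256 to 0, so its scale and direction are known and no centring was applied. Probe positions in the files refer to the mouse build mm8, per the file headers. Coordinates were not used here.

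Values on the log2 scale were computed here from the deposited intensity columns, as log2 of Cy5 over Cy3. The background was corrected by normexp with an offset of 50. Each array was normalized by loess, with control spots at weight 0. Spots marked as non-uniform or as population outliers were set to missing, 0.398% of values. Of 45018 features per array, 1639 were controls, and the rest held 41174 probes. Probes with Cy5 well above background on at least 4 of the 36 arrays were kept, 34229 in all. Names came from the accession for 23374 probes, from a current symbol for 6733 and from a synonym for 2919, through a RefSeq gene table. The other 8148 probes kept the name in the file. Each gene name was represented by its brightest probe over all arrays, which gave 22938 genes. A gene whose group had no array well above background has only a bound on its fold there, which is written as at least that fold; it comes from the single channels and is open to dye bias.

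The ages were day 0 (1 KO and 1 WT), day 1 (4 and 4), day 2 (5 and 5), day 3 (2 and 2), day 7 (4 and 4) and day 14 (2 and 2). Differences were tested in limma 3.58.1 under R 4.3.3 with statmod 1.5.0, jsonlite 2.0.0 and version 1.17.8 of the data.table package. KO against WT over all ages was fitted with age as an additive factor. The single ages, the postnatal changes in WT and the contrast of late with early ages came from 1 fit of the 12 genotype-by-age groups, which share an estimate of the spread. The late against early contrast is the mean KO minus WT difference on days 7 and 14 minus that on days 0, 1, 2 and 3. An F test covered the 5 interaction terms. The lone animals of day 0 were assumed to vary like the other groups. Benjamini-Hochberg adjusted p under 0.05 was the threshold. All p-values are two-sided.

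Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over 35 lists, or over the 175 tests of 35 lists at 5 ages. Each was repeated with an estimated correlation. Lists covered calcineurin subunits, NFAT factors and calcineurin regulators, proximal tubule, thick ascending limb, distal convoluted tubule, collecting duct principal cells, intercalated cells, podocytes, nephron progenitors, early nephron and ureteric tip, renal stroma, smooth muscle, urothelium, extracellular matrix and fibrosis, tubular injury and macrophages. The remaining lists were chemokines and cytokines, lymphocytes, neutrophils, complement and acute phase, endothelium, erythroid cells, adrenal gland, adipocytes, liver, skeletal muscle, cell cycle, immediate early genes, interferon response, hypoxia response, fatty acid oxidation, oxidative phosphorylation, osmotic response, hedgehog, BMP and Wnt signalling, and renin-angiotensin and vasoactive genes. Pvalb is in the distal convoluted tubule and skeletal muscle lists, Akr1b3 in the osmotic and vasoactive lists, and Aqp2 and Slc14a2 in the osmotic and collecting duct lists. Pck1 is in the proximal tubule and adipocyte lists, and Cxcl10 in the chemokine and interferon lists. The sex-linked gene Xist served only as a check, because the labels give no sex.

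The tests, the gene lists, the other settings to try and the rule for named genes were fixed before the data were examined. Over all ages, the 12 highest and 12 lowest log2 differences were named among genes past the threshold with 1 sign on days 1, 2, 3, 7 and 14. Single ages and the late against early contrast took the 5 highest and 5 lowest past the threshold, with none for day 0. WT day 7 against day 1 took 8 and 8, and WT day 14 against day 1 took 5 and 5. Genes known only by an accession or clone were counted and not named. Some genes that the rule takes are not reported here. Up to 4 members per list with the smallest adjusted p were named as examples, and calcineurin subunits always.

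From 64.2% to 79.7% of the non-control features were well above background in Cy5, with medians of Cy5 intensity from 71.92 to 234.8 per array. No Cy5 feature was saturated. The precision of each value is limited by the number of arrays. The files place the 36 arrays on 10 slides with up to 4 arrays each, scanned on 4 days. Slide accounted for 53.2% of the residual sum of squares of the 12-group fit and scan day for 42.4%. Each slide was scanned on a single day, so the share of scan day is contained in that of slide. With 10 slides against 4 scan days, slide also takes up more of the spread by chance. All 4 arrays of day 14 lay on 1 slide. On day 7 only 1 slide held both genotypes.

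The recovery of known changes was tested on simulated data with 50 genes per size. The noise took each gene's residual spread but was independent between genes and arrays, without slide or scan day effects. The shares below therefore hold only for data of that kind. Over all ages, 78% of genes changed by 0.5 on the log2 scale were recovered and 96% of those changed by 1. For a change of 1 the share was 30% on day 0, 78% on day 1, 84% on day 2, 58% on day 3, 78% on day 7 and 48% on day 14. For a change of 2 it was 78%, 94%, 96%, 92%, 96% and 90% in the same order. For the late against early contrast it was 72% at 1 and 96% at 2, and for the interaction test, simulated as a change on day 7 only, 50% and 92%. For WT day 7 against day 1 it was 80% and 96%, and for WT day 14 against day 1 it was 74% and 94%.

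Alternatives were no background correction, the processed scanner intensities centred on the median, median centring in place of loess, Cy5 alone scaled to each array's 75th percentile, the series matrix, no filter or a filter at 18 arrays, the mean over probes, trended robust moderation, array quality weights, blocks for slide, scan day and replicate number, within-scan fits, Xist as a covariate, equal weights for ages, days 1, 2 and 7 only, fits on 1 age, and each array left out in turn. Scaling average intensities between arrays (Aquantile) moves no log ratio, so it says nothing here. After the data were seen, 7 more were added: slide or scan day as a fixed block and the third scan day alone for the WT ages, leaving out the 2 arrays with over 400 non-uniform Cy5 spots, leaving out these and WT replicate 7, the mean of the adipocyte list as a covariate, leaving out days 0 and 14, Xist as a covariate for the genes of day 7, and an estimated correlation for the lists that a slide or scan day block called. The threshold of 400 spots was also chosen then.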

Results

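Kidneys of mice labelled as calcineurin beta 1 knockouts and of wild-type mice were compared from birth to day 14. There were 18 KO and 18 WT animals, with 1 animal of each genotype on day 0, 4 on day 1, 5 on day 2, 2 on day 3, 4 on day 7 and 2 on day 14. Each array gave the ratio of kidney RNA to a common reference RNA for 22938 genes. A median of 76% of features per array lay well above background. Correlations of an array with its own group ran from 0.83 (WT replicate 7, day 2) to 0.978. Animals with high Xist, a transcript of female cells, were 9 of 18 in KO and 12 of 18 in WT. On day 14 both KO arrays had low and both WT arrays high Xist, so genotype and sex cannot be told apart at that age.

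Of the calcineurin genes, none passed the test over all ages at its brightest probe. For Ppp3r1, taken as the knocked-out gene, the brightest probe differed by −0.14 on the log2 scale (SE 0.116, adjusted p = 0.571), and the sign turned to 0.15 with Cy5 alone. The other probes of Ppp3r1 were lower in KO, by −0.44 (SE 0.0903, adjusted p = 0.00365 over all kept probes) and −0.76 (SE 0.116, adjusted p = 0.000274). On day 7 the brightest probe ranged from −0.625 to 0.482 in KO and from −0.401 to 0.0745 in WT, and on day 0 it was −0.51 in KO and 0.97 in WT. The deleted part of the gene is not given in the sources used here, so a probe outside it would check nothing. Whether the knockout was limited to some kidney cells is not given either. The catalytic subunits Ppp3ca (0.38, SE 0.133, adjusted p = 0.0819), Ppp3cb (−0.24, SE 0.0923, adjusted p = 0.126) and Ppp3cc (0.02, adjusted p = 0.954) and the testis-type regulatory subunit Ppp3r2 (−0.03, adjusted p = 0.702) did not pass the test. The other probes of Ppp3cb pointed the other way (0.20, 0.05 and 0.04). Those of Ppp3cc gave 0.16 and −0.00089, and that of Ppp3ca gave 0.12. None of these passed. Rcan1, a calcineurin inhibitor whose transcription calcineurin and NFAT raise, fell by 0.50 in KO over all ages (SE 0.113, adjusted p = 0.00658). On day 7 it fell by 0.94 (SE 0.232, adjusted p = 0.0205), with KO arrays between 0.0384 and 0.916 and WT arrays between 1.12 and 1.79.

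Over all ages, Sprr2f, of the small proline-rich proteins of stressed epithelia, rose by 3.36 on the log2 scale (10.3-fold, SE 0.462, adjusted p = 9.14e-05), from 2.42 ± 1.90 in WT to 5.79 ± 1.52 in KO (SD, n = 18 each). Slc12a3, the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule, fell by 2.15 (SE 0.300, adjusted p = 1.10e-04), with 13 of 18 KO and 16 of 18 WT arrays above background. In all 1544 of 22938 genes changed, 650 higher and 894 lower in KO. The split was 31 higher and 124 lower with median centring in place of loess.

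The keratins Krt20 and Krt19 rose by 1.84 (SE 0.281, adjusted p = 2.32e-04) and 1.42 (SE 0.213, adjusted p = 1.98e-04). Pmaip1, a pro-apoptotic protein of the BCL2 family, rose by 1.57 (SE 0.221, adjusted p = 1.10e-04). The macrophage scavenger receptors Cd163 (1.14, adjusted p = 3.23e-04) and Marco (1.10, adjusted p = 0.0138) rose too, as did the gasdermin Gsdmc (1.22, adjusted p = 0.00430), the surface protein Ly6d (1.18, adjusted p = 0.0131) and melanotransferrin, Meltf (1.13, adjusted p = 0.00141). Sox9, a transcription factor of growing and regenerating tubule cells, rose by 1.08 (SE 0.260, adjusted p = 0.0101), and by 0.87 with slide as a block (adjusted p = 0.0519). The remaining genes of the highest 12 were 1200016E24Rik (1.35, adjusted p = 0.00431) and Olfr1065, annotated as an olfactory receptor (1.07, adjusted p = 0.00149).

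Among genes that fell, S100g, a calcium-binding protein of distal tubule cells, changed by −1.65 (SE 0.258, adjusted p = 2.78e-04) and Egf, made in the thick ascending limb and distal tubule, by −1.55 (SE 0.302, adjusted p = 0.00191). The betaine transporter Slc6a12, which cells use to take up an organic osmolyte, fell by 1.51 (SE 0.189, adjusted p = 3.32e-05). Transporters of organic solutes fell: Slc22a7 (−1.53, adjusted p = 0.00193), the lactate carrier Slc5a8 (−1.46, adjusted p = 0.00753), the amino acid carrier Slc7a13 (−1.40, adjusted p = 0.00145) and Slc16a4 (−1.38, adjusted p = 0.00264). Enzymes that fell were the acyltransferase Mogat2 (−1.74, adjusted p = 2.76e-04), the mitochondrial dimethylglycine dehydrogenase Dmgdh (−1.45, adjusted p = 0.00236) and the brush border protease Mep1b (−1.43, adjusted p = 0.00185). Ranbp3l fell by 1.71 (SE 0.284, adjusted p = 4.70e-04). With slide as a block 1637 genes passed, 778 higher and 859 lower, and with scan day as a block 2084, 997 higher and 1087 lower. Of the 1544 genes, 1134 and 1335 were among them. Within single scan days the counts were 0 (1914 at an unadjusted p under 0.05, limma, 5 KO and 3 WT arrays), 1 (6 and 6) and 13 (6 and 5), and the last scan day had no age with both genotypes.

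**Figure D1:**
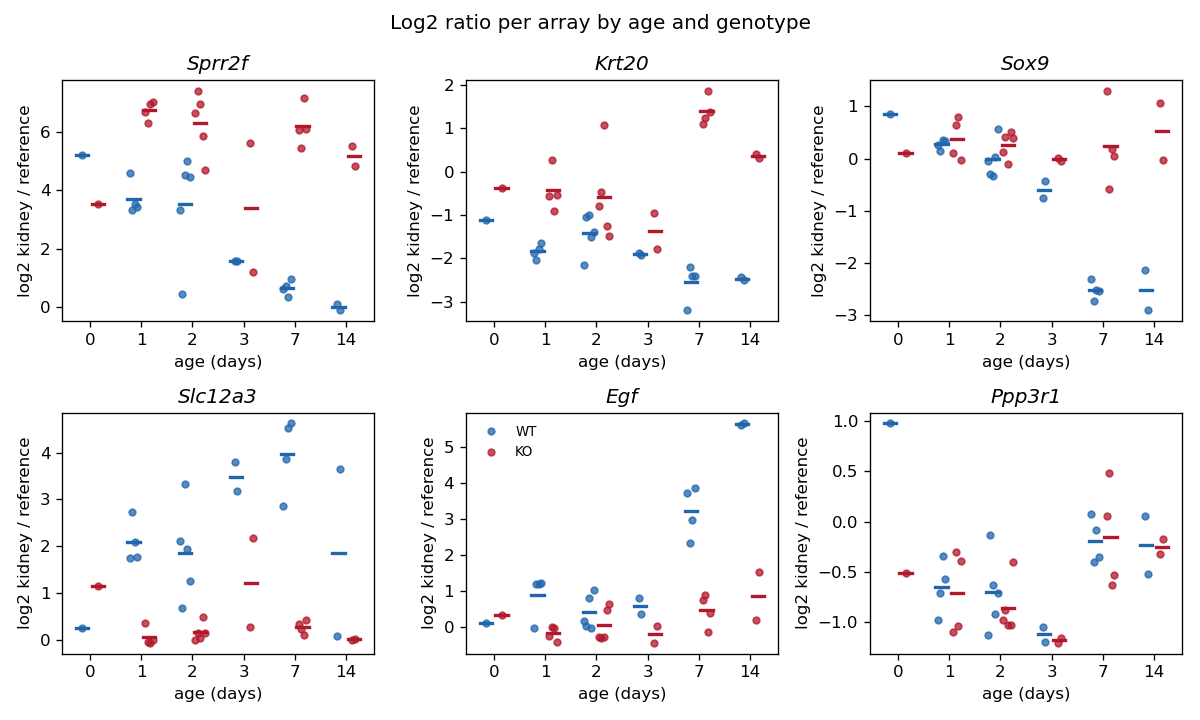
Log2 ratio of kidney RNA to reference RNA (vertical axis) by age in days (horizontal axis) for Sprr2f, Krt20, Sox9, Slc12a3, Egf and Ppp3r1. Each point is 1 animal, WT in blue and KO in red, and each bar is the group mean. On day 7 Sprr2f averaged 6.20 in KO and 0.67 in WT, while the groups overlapped for Ppp3r1.

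Of the 35 gene lists, 16 passed the test over all ages, and of these the distal convoluted tubule list alone passed with an estimated correlation. Its mean was −0.77 (adjusted p = 4.40e-11, and 0.0209 with an estimated correlation). Of its 10 members 6 fell, 8 when adjusted over the list alone, with Wnk4, a kinase that regulates Slc12a3 (−0.51, adjusted p = 2.51e-04), and the calcium buffer Pvalb (−1.19, adjusted p = 0.00182) beside Slc12a3 and S100g. Pvalb was above background on no KO array of days 1, 7 and 14, where WT was higher at least 3.62-fold, 3.38-fold and 4.12-fold. Oxidative phosphorylation genes, of the mitochondrial respiratory chain, fell by a mean of 0.36 (adjusted p = 5.77e-21, and adjusted p = 0.0517 with an estimated correlation). Of 27 members 20 were lower (26 adjusted over the list alone), such as the ATP synthase subunits Atp5o (−0.47), Atp5b (−0.48) and Atp5c1 (−0.46). Proximal tubule genes had a mean of −0.56 (adjusted p = 6.72e-12, and adjusted p = 0.165 with an estimated correlation). Of 29 measured, 12 fell (17 adjusted over the list alone), among them the water channel Aqp1 (−0.61), the dicarboxylate carrier Slc13a3 (−0.84), the phosphate carrier Slc34a3 (−1.36) and Dpep1 (−0.86). Fatty acid oxidation had a mean of −0.24 (adjusted p = 3.37e-05, and adjusted p = 0.298 with an estimated correlation), with 5 of 16 lower (6 adjusted over the list alone), including Cpt2 (−0.36) and Hadha (−0.34). The thick ascending limb list had a mean of −0.39 (adjusted p = 3.26e-04, and adjusted p = 0.265 with an estimated correlation), with Egf and the prostaglandin receptor Ptger3 (−0.75) lower of 12 measured and 5 lower when adjusted over the list alone. Beside these lists the adipocyte list differed by −0.12 (adjusted p = 0.811) over all ages. This mean pools opposite signs, since the list was higher in KO on day 2 and lower on day 14, as given below.

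The osmotic response list had a mean of −0.46 (adjusted p = 0.0039, and adjusted p = 0.164 with an estimated correlation). Of its 10 members 4 fell, including Slc6a12, Ranbp3l and aldose reductase, Akr1b3 (−1.06), and the taurine carrier Slc6a6 rose (0.42), as many as when adjusted over the list alone. Hypoxia genes had a mean of −0.16 (adjusted p = 0.00667, and adjusted p = 0.127 with an estimated correlation), with 4 of 14 lower, such as Pdk1 (−0.47) and Egln3 (−0.54), and 5 adjusted over the list alone. The liver marker list, a check for other tissue, had a mean of −0.26 (adjusted p = 0.00386, and adjusted p = 0.346 with an estimated correlation), with Apoa2 (−0.62), Ttr (−0.58) and Serpina1c (−0.44) lower of 12, the same number when adjusted over the list alone. Cell cycle genes had a mean of −0.14 (adjusted p = 0.00468, and adjusted p = 0.703 with an estimated correlation) with 0 of 25 members past the test in limma, 0 adjusted over the list alone and 4 at an unadjusted p under 0.05. Endothelium had a mean of −0.16 (adjusted p = 0.0468, and adjusted p = 0.703 with an estimated correlation) with 0 of 13 in limma, 0 adjusted over the list alone and 3 at such an unadjusted p. The endothelium call was lost with slide as a block (adjusted p = 0.08) and with scan day as a block (adjusted p = 0.104).

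The lists higher in KO were tubular injury, immediate early genes, macrophages, chemokines and cytokines, urothelium, and extracellular matrix and fibrosis. Tubular injury genes had a mean of 0.37 (adjusted p = 3.23e-09, and adjusted p = 0.0594 with an estimated correlation). Of 24 measured, 11 rose and 1 fell (13 and 2 adjusted over the list alone), with the TWEAK receptor Tnfrsf12a (0.93), Krt18 (1.03) and galectin 3, Lgals3 (0.60), among the former. Immediate early genes had a mean of 0.34 (adjusted p = 3.23e-09, and adjusted p = 0.0594 with an estimated correlation), with 10 of 18 higher and 1 lower (13 and 2 adjusted over the list alone), including Atf3 (0.57), Junb (0.66) and Egr1 (0.82). Macrophage markers had a mean of 0.26 (adjusted p = 1.21e-05, and adjusted p = 0.105 with an estimated correlation), with Cd14 (0.67), Ctss (0.55) and Fcgr3 (0.51) higher of 20, and 8 adjusted over the list alone. Chemokines and cytokines had a mean of 0.28 (adjusted p = 1.97e-05, and adjusted p = 0.216 with an estimated correlation). Of 17 measured, 3 were higher and 6 adjusted over the list alone. The 3 were Il34, a ligand of the macrophage receptor Csf1r (1.02, adjusted p = 3.32e-05), Cxcl16 (0.77) and Csf1 (0.30). Urothelium markers had a mean of 0.50 (adjusted p = 1.40e-05, and adjusted p = 0.104 with an estimated correlation), with 5 of 12 higher (6 adjusted over the list alone), among them Krt20, Gsdmc and the basal keratin Krt5 (0.91). Extracellular matrix and fibrosis genes had a mean of 0.16 (adjusted p = 0.0210, and adjusted p = 0.638 with an estimated correlation). Timp1 (0.78) and Mmp14 (0.31) rose and Fbn1 (−0.45) fell of 26, with 9 higher and 2 lower adjusted over the list alone, and the call was lost with slide (adjusted p = 0.105) or scan day (adjusted p = 0.104) as a block.

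Within the first, the second and the third scan day the mean of oxidative phosphorylation was −0.691, −0.247 and −0.208, of the proximal tubule −0.808, −0.264 and −0.582 and of the distal convoluted tubule −0.624, −0.499 and −0.843. Tubular injury gave 0.592, 0.113 and 0.555, macrophages 0.395, 0.232 and 0.226 and urothelium 0.441, 0.408 and 0.477. Immediate early genes gave 0.592, 0.170 (adjusted p = 0.0503) and 0.465, and chemokines 0.373, 0.00842 (adjusted p = 0.795) and 0.471. Inside slides, oxidative phosphorylation lay below 0 in all 10 comparisons (mean −0.263, SE 0.0913), the distal convoluted tubule in 9 (−0.589, SE 0.151) and the proximal tubule in 8 (−0.357, SE 0.245). Fatty acid oxidation lay below 0 in 6 (mean −0.184, SE 0.126). Tubular injury lay above 0 in 6 (mean 0.263) and immediate early genes in 9 (0.276).

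The other 19 lists did not pass the test over all ages. Members of the NFAT and calcineurin regulator list that changed included Rcan1 and the kinase Dyrk1a (0.20, adjusted p = 0.0453). The list had adjusted p = 0.922, with a mean of −0.03, a median of 0.02 and a test that pointed up. The calcineurin subunit list had a mean of −0.00281 (adjusted p = 0.815). Of 16 interferon genes Ifi44 (−0.59), Rsad2 (−0.65) and Isg15 (−0.47) fell, with a list mean of −0.09 (adjusted p = 0.232). In the vasoactive list (mean −0.13, adjusted p = 0.255) endothelin 1, Edn1, rose (0.72, adjusted p = 0.00556) and Ace fell (−0.50, adjusted p = 0.0411), as did Akr1b3. Smooth muscle had a mean of 0.17 (adjusted p = 0.226) with Synm higher (0.46), complement and acute phase 0.09 (adjusted p = 0.497) with C3 higher (0.79), and renal stroma 0.05 (adjusted p = 0.538) with Meis1 (0.35) and Foxd1 (0.51) higher. Intercalated cells had a mean of −0.11 (adjusted p = 0.497) with Aqp6 lower (−0.65), and collecting duct principal cells −0.09 (adjusted p = 0.520) with the vasopressin-regulated water channel Aqp2 lower (−0.38). Lymphocytes had a mean of 0.02 (adjusted p = 0.906) with Cd8a lower (−0.17), and skeletal muscle 0.06 (adjusted p = 0.838) with Pvalb lower. Podocytes had a mean of −0.01 and a median of −0.03 with a test that pointed up (adjusted p = 0.915), and Wt1 rose (0.37).

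Nephron progenitors (mean −0.03, adjusted p = 0.838), the early nephron and ureteric tip (mean 0.02, median −0.02, test down, adjusted p = 0.922) and hedgehog, BMP and Wnt signalling (mean −0.00823, median 0.01, test down, adjusted p = 0.922) had no member past the test in limma. The same held for erythroid cells (mean −0.10, adjusted p = 0.226), adrenal gland (0.12, adjusted p = 0.232), neutrophils (0.05, adjusted p = 0.749) and adipocytes. At an unadjusted p under 0.05 stood 1 of 12 nephron progenitor genes, 2 of 14 of the early nephron and ureteric tip, 2 of 11 erythroid genes and none of the adrenal, neutrophil, adipocyte or signalling genes.

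**Figure D2:**
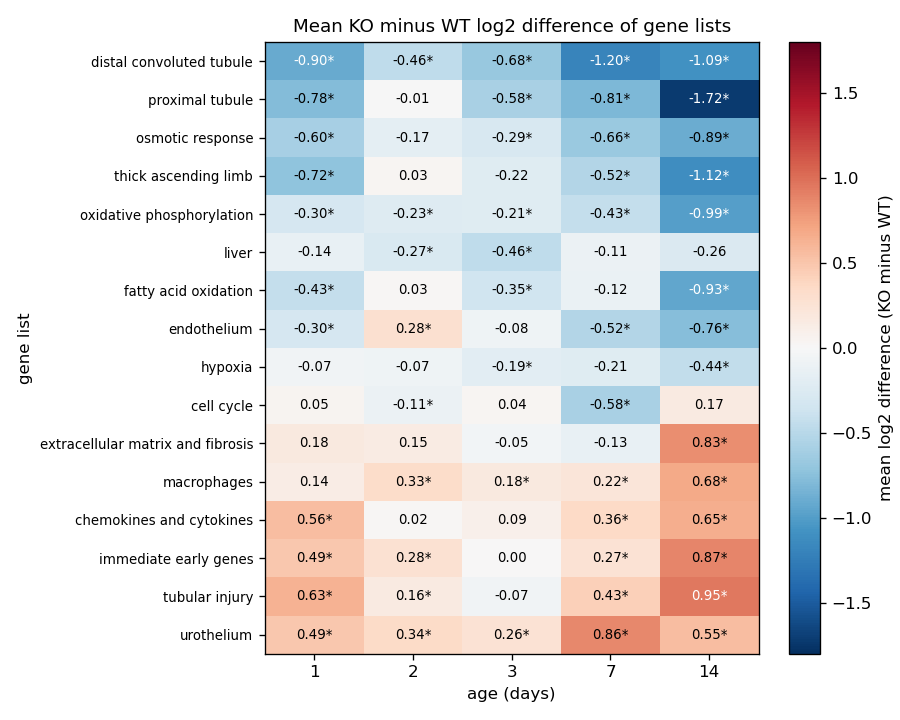
Mean KO minus WT log2 difference (colour) of the 16 gene lists called over all ages (vertical axis) on days 1, 2, 3, 7 and 14 (horizontal axis). An asterisk stands for an adjusted p under 0.05 with the preset correlation. Oxidative phosphorylation and the distal convoluted tubule were lower in KO at each of the 5 ages, with means on day 14 of −0.99 and −1.09.

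On day 1, the keratins Krt19, Krt18 and Krt8 rose by 2.03 (SE 0.414, adjusted p = 0.0352), 1.70 (SE 0.279, adjusted p = 0.00663) and 1.53 (SE 0.235, adjusted p = 0.00488). Pmaip1 rose by 2.07 (SE 0.313, adjusted p = 0.00488) and the oncostatin M receptor Osmr by 1.39 (SE 0.261, adjusted p = 0.0239). Ranbp3l (−2.78, adjusted p = 0.0335), the sugar carrier Slc5a10 (−2.47, adjusted p = 0.0176), Mep1b (−2.38, adjusted p = 0.0335), pendrin, Slc26a4 (−2.06, adjusted p = 0.0296), and Abca13 (−2.03, adjusted p = 0.0296, above background on 1 of 4 KO arrays) fell. In all 59 genes changed, 31 higher and 28 lower, with 22 passing with slide as a block and 64 with scan day, of which 18 and 42 were among the 59. The slide block ended the calls of Krt19 (1.97, adjusted p = 0.0611), Osmr (1.39, adjusted p = 0.057), Mep1b (−2.38, adjusted p = 0.125) and Slc26a4 (−1.93, adjusted p = 0.102), and the scan block those of Krt19 (1.95, adjusted p = 0.0582) and Mep1b (−2.31, adjusted p = 0.0522). The split was 46 higher and 66 lower with scanner-processed intensities, 85 and 119 with Cy5 alone, and 0 and 1 with median centring, where the median difference of all genes was −0.438 (−0.00488 with loess). Without KO replicate 2 the count was 270, and without KO replicate 3 it was 7.

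Tubular injury genes had a mean of 0.63 on day 1 (adjusted p = 3.39e-12, and 0.036 with an estimated correlation), with 4 of 24 members higher and 12 adjusted over the list alone. Chemokines had a mean of 0.56 (adjusted p = 5.49e-09, and adjusted p = 0.123 with an estimated correlation), with Il34 higher (1.26). Immediate early genes had 0.49 (adjusted p = 1.62e-08, and adjusted p = 0.123 with an estimated correlation), with Junb (1.06) and Ccn1 (1.28) higher. The proximal tubule list had a mean of −0.78 (adjusted p = 1.87e-11, and adjusted p = 0.171 with an estimated correlation). The distal convoluted tubule had −0.90 (adjusted p = 2.60e-07, and adjusted p = 0.0872 with an estimated correlation) and the thick ascending limb −0.72 (adjusted p = 6.27e-07, and adjusted p = 0.137 with an estimated correlation). Oxidative phosphorylation (−0.30), fatty acid oxidation (−0.43), podocytes (−0.53), intercalated cells (−0.52), osmotic response (−0.60), vasoactive genes (−0.31) and endothelium (−0.30) passed as lower, and urothelium (0.49), neutrophils (0.27) and adrenal gland (0.59) as higher. With an estimated correlation the adjusted p of these 10 lists ran from 0.246 to 0.661. In the adrenal list KO replicate 3 stood at 2.47 and the other KO arrays of day 1 between 0.631 and 0.782. The call of neutrophils was lost with slide (adjusted p = 0.107) and scan day (adjusted p = 0.0722) as blocks, and both blocks called extracellular matrix and fibrosis higher (adjusted p = 0.0436 and 0.0303, and adjusted p = 0.749 and 0.698 with an estimated correlation).

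On days 2 and 3 no single gene passed the test in limma, and gene lists passed. On day 2 the smallest adjusted p was 0.796, with 1052 genes at an unadjusted p under 0.05, and on day 3 there were 0.506% of genes at such a p. On day 2 oxidative phosphorylation (mean −0.23, adjusted p = 1.22e-10, and adjusted p = 0.141 with an estimated correlation) and the distal convoluted tubule (−0.46, adjusted p = 1.17e-05, and adjusted p = 0.123 with an estimated correlation) were lower in KO. Immediate early genes (0.28, adjusted p = 6.28e-06, and adjusted p = 0.196 with an estimated correlation) and macrophages (0.33, adjusted p = 7.55e-05, and adjusted p = 0.169 with an estimated correlation) were higher. Liver (−0.27) and cell cycle (−0.11) passed as lower, and adipocytes (0.56), endothelium (0.28), tubular injury (0.16), podocytes (0.24) and urothelium (0.34) as higher, at an adjusted p of 0.488 to 0.776 with an estimated correlation. The adipocyte list stood at 1.81 and 1.83 in KO replicates 6 and 7 and no higher than 0.985 in WT of that day. The liver list stood at 1.75 and 1.71 in WT replicates 6 and 8, at 0.232 to 0.377 in the other WT arrays and at 0.418 to 0.897 in KO. The direction of endothelium turned under 5 other settings, such as array quality weights. The slide block ended the call of podocytes (adjusted p = 0.0546) and the scan block that of urothelium (adjusted p = 0.0608), and both called intercalated cells higher (adjusted p = 0.0301 and 0.0303, and adjusted p = 0.761 and 0.744 with an estimated correlation).

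On day 3 the proximal tubule (−0.58, adjusted p = 6.44e-14, and adjusted p = 0.132 with an estimated correlation), the distal convoluted tubule (−0.68, adjusted p = 4.64e-08, and adjusted p = 0.0752 with an estimated correlation), fatty acid oxidation (−0.35) and oxidative phosphorylation (−0.21) were lower in KO. Liver (−0.46), hypoxia (−0.19) and osmotic response (−0.29) passed as lower and macrophages (0.18) and urothelium (0.26) as higher. For the last 7 lists the adjusted p with an estimated correlation ran from 0.236 to 0.525. The direction of macrophages turned without KO replicate 11, which left KO replicate 12 as the only KO array of that day, and the call of urothelium was lost with slide (adjusted p = 0.0881) and scan day (adjusted p = 0.0766) as blocks. On day 0, with 1 array per genotype, 17 genes passed (15 higher, 2 lower), and 48 and 72 with slide and scan day as blocks (15 and 17 of them among the 17). There Sprr2f was 3.54 in KO and 5.21 in WT, and Slc12a3 was 1.14 in KO and 0.26 in WT. The arrays of day 0 shared a slide and a scan day, so neither block could change a difference of that day. How many genes passed on day 0 varied widely with the processing, down to none with median centring.

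On day 7, Sprr2f rose by 5.53 (46.3-fold, SE 0.771, adjusted p = 9.46e-05), from 0.67 ± 0.257 to 6.20 ± 0.712 (SD, 4 arrays each), and Krt20 by 3.96 (15.5-fold, SE 0.368, adjusted p = 7.74e-07). Sox9 rose by 2.76 (SE 0.283, adjusted p = 2.51e-06), Pmaip1 by 2.75 (SE 0.313, adjusted p = 7.10e-06) and the cytochrome P450 gene Cyp2j13 by 2.84 (SE 0.573, adjusted p = 0.00474). Slc12a3 fell by 3.70 (SE 0.540, adjusted p = 1.67e-04), Egf by 2.75 (SE 0.347, adjusted p = 2.80e-05) and Mogat2 by 3.09 (SE 0.430, adjusted p = 9.46e-05). The retinaldehyde dehydrogenase Aldh1a3 fell by 4.17 (SE 0.993, adjusted p = 0.0170) and Akr1b3 by 2.76 (SE 0.588, adjusted p = 0.00812). In all 867 genes changed, 337 higher and 530 lower, and 557 and 557 with Cy5 alone. Far fewer passed with median centring or in a fit on day 7 alone, and more with array quality weights, as given below. With slide as a block 299 passed (109 higher, 190 lower), and with scan day 858. Of these, 163 and 382 were among the 867. The slide block ended the calls of Cyp2j13 (3.36, adjusted p = 0.0957), Slc12a3 (−2.78, adjusted p = 0.166), Aldh1a3 (−4.11, adjusted p = 0.315) and Akr1b3 (−2.82, adjusted p = 0.266), and the scan block those of Aldh1a3 (−4.12, adjusted p = 0.131) and Akr1b3 (−2.83, adjusted p = 0.102). The count was 374 without WT replicate 14, 393 without WT replicate 16, 405 without WT replicate 15, 436 without KO replicate 14 and 1548 without WT replicate 13.

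Among gene lists on day 7, the distal convoluted tubule had a mean of −1.20 (adjusted p = 4.36e-07, and adjusted p = 0.0872 with an estimated correlation), with 5 members lower, including S100g (−2.74). The proximal tubule had a mean of −0.81 (adjusted p = 2.64e-09, and adjusted p = 0.246 with an estimated correlation), with 6 members lower, such as Slc34a3 (−2.47), Slc13a3 (−1.36), the organic anion carrier Slc22a8 (−1.17) and Aqp1 (−0.97). Oxidative phosphorylation had a mean of −0.43 (adjusted p = 6.84e-10, and adjusted p = 0.165 with an estimated correlation) and cell cycle −0.58 (adjusted p = 3.58e-08, and adjusted p = 0.360 with an estimated correlation), with the replication factor Mcm5 lower (−0.83). Tubular injury had a mean of 0.43 (adjusted p = 4.12e-05, and adjusted p = 0.169 with an estimated correlation), with 7 members higher, including Tnfrsf12a (1.40) and Lgals3 (0.86), and 2 lower, including the small heat shock protein Cryab (−1.70). Urothelium (0.86), immediate early genes (0.27), chemokines (0.36) and macrophages (0.22) passed as higher, with Atf3 (0.84), Cxcl16 (1.27) and Itgam (0.66) among their members that rose. Endothelium (−0.52), the thick ascending limb (−0.52) and osmotic response (−0.66) passed as lower, with Slc6a12 lower (−2.58) and Slc6a6 higher (0.94) in the last. For these 7 lists the adjusted p with an estimated correlation ran from 0.246 to 0.488. As a block slide ended the call of the proximal tubule (adjusted p = 0.156), scan day those of macrophages (adjusted p = 0.138) and chemokines (adjusted p = 0.184). Slide and scan day each ended the calls of osmotic response (adjusted p = 0.687 and 0.566) and the thick ascending limb (adjusted p = 0.725 and 0.566). Both blocks called 4 further lists as lower, and none of them passed with an estimated correlation. The smallest p was that of extracellular matrix and fibrosis (adjusted p = 4.45e-07 with slide and 1.37e-07 with scan day, and adjusted p = 0.322 and 0.240 with an estimated correlation), which was higher over all ages. The others were hedgehog, BMP and Wnt signalling (adjusted p = 0.00123 and 0.000312, and adjusted p = 0.340 and 0.240 with an estimated correlation), renal stroma (adjusted p = 0.0270 and 0.0330, and 0.505 and 0.501) and erythroid cells (adjusted p = 0.0443 and 0.0381, and 0.498 and 0.458).

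On day 14, Dnase1, a secreted nuclease abundant in kidney, fell by 5.42 (SE 0.590, adjusted p = 2.75e-06) and Egf by 4.76 (SE 0.491, adjusted p = 1.14e-06). The brown fat genes Ucp1 (−4.91, adjusted p = 0.00365, above background on 1 of 2 KO arrays), Cidea (−4.35, adjusted p = 0.0421) and Cox8b (−4.25, adjusted p = 0.0277) fell. Sprr2f rose by 5.18 (SE 1.09, adjusted p = 0.00483, above background on 1 of 2 WT arrays) and Sox9 by 3.04 (SE 0.401, adjusted p = 3.76e-05). The smooth muscle protein gene Tagln rose by 3.01 (SE 0.526, adjusted p = 9.64e-04), the annexin Anxa13 by 2.90 (SE 0.426, adjusted p = 1.43e-04) and Cyp2j13 by 3.45 (SE 0.811, adjusted p = 0.0118). Slc12a3 was 3.65 and 0.08 on the WT arrays. In all 1039 genes changed, 268 higher and 771 lower. The split was 518 and 768 without background correction, 586 and 510 with scanner-processed intensities, 614 and 657 with the series matrix, 869 and 801 with Cy5 alone, and 5 and 70 with median centring, where the median difference of all genes was −0.249 (−0.0187 with loess). All 4 arrays shared a slide and a scan day, so neither block can change a difference of day 14. Egf, for example, stayed at −4.76 with each block. With slide and scan day as blocks 1690 and 1959 genes passed, 1008 and 1039 of them among the 1039. These counts moved only through the SE and are no check of slide or scan day. Without KO replicate 17, 92 genes were higher and 149 lower, and without WT replicate 17 the count was 310. With the adipocyte list mean as a covariate, chosen after seeing the data, it was 433, with 124 higher and 309 lower.

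On the 2 WT arrays of day 14 the adipocyte list stood at 2.84 and 3.00, and on the KO arrays at 1.25 and 0.689, a list difference of −1.95 (adjusted p = 8.18e-05, and adjusted p = 0.246 with an estimated correlation). Beside it oxidative phosphorylation fell by a mean of 0.99 (adjusted p = 3.51e-22, and 0.036 with an estimated correlation), with 15 members lower. Fatty acid oxidation had a mean of −0.93 (adjusted p = 1.86e-08, and adjusted p = 0.169 with an estimated correlation), with 5 lower, such as Decr1 (−1.43). The proximal tubule had a mean of −1.72 (adjusted p = 5.86e-19, and adjusted p = 0.0953 with an estimated correlation), with 15 members lower, including Cyp2e1 (−3.40), the amino acid carrier Slc6a19 (−3.53), Slc34a3 (−3.46) and Slc22a8 (−2.29). Tubular injury genes had a mean of 0.95 (adjusted p = 1.34e-11, and 0.036 with an estimated correlation), with 7 of 24 members higher, such as Krt18 (2.02) and Lgals3 (1.34). Immediate early genes had a mean of 0.87 (adjusted p = 8.37e-10, and adjusted p = 0.0953 with an estimated correlation), with Egr1 (2.14), Egr2 (2.66) and Junb (1.79) higher. Extracellular matrix and fibrosis genes had a mean of 0.83 (adjusted p = 1.04e-09, and adjusted p = 0.123 with an estimated correlation), with Tgfbi (2.74), Timp1 (2.12), Col5a1 (1.47) and Mmp14 (1.40) higher. Macrophages had a mean of 0.68 (adjusted p = 2.45e-06, and adjusted p = 0.123 with an estimated correlation), with Ms4a7 higher (1.68). Chemokines had 0.65 (adjusted p = 2.63e-05, and adjusted p = 0.246 with an estimated correlation), with Il34 higher (2.13).

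The distal convoluted tubule (−1.09) and the thick ascending limb (−1.12) passed as lower on day 14 too, with Wnk4 (−1.18) and Ptger3 (−2.01) among their members that fell. Endothelium (−0.76), osmotic response (−0.89) and hypoxia (−0.44) also passed as lower. Smooth muscle (0.75), urothelium (0.55) and renal stroma (0.43, with Penk 1.46 and Dcn 1.25 higher) passed as higher. For these 8 lists the adjusted p with an estimated correlation ran from 0.126 to 0.459. Over the 5 ages 65 of 175 list tests passed, and 3 of them with an estimated correlation.

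Days 7 and 14 shared no arrays, and 62 genes were higher and 187 lower on both, where independent lists of these sizes would share 3.94 and 17.8. Day 1 and day 7 shared 9 higher and 9 lower genes (0.455 and 0.647 from independent lists), and day 1 and day 14 shared 13 and 17 (0.362 and 0.941).

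The genotype difference itself changed between early and late ages for 337 genes, 70 with a higher and 267 with a lower difference on days 7 and 14 than on days 0 to 3. The late mean includes day 14, where genotype and sex cannot be told apart and fat markers were high on the WT arrays. Xist was not a covariate for this contrast or the interaction test. The early mean includes day 0, with 1 array per genotype, where Sprr2f was 3.54 in KO and 5.21 in WT. The difference of Sox9 was larger at the late ages by 2.84 (SE 0.315, adjusted p = 7.08e-06), of Krt20 by 2.52 (SE 0.409, adjusted p = 0.0012), and of Anxa13 by 2.05 (SE 0.335, adjusted p = 0.00127). That of Sprr2f was larger by 3.86 (SE 0.858, adjusted p = 0.0180) and of Cyp2j13 by 2.78 (SE 0.638, adjusted p = 0.0223). It was lower for Egf by −3.26 (SE 0.386, adjusted p = 1.62e-05), and Dnase1 by −3.15 (SE 0.464, adjusted p = 3.70e-04). It was also lower for the potassium channel Kcnt1 by −2.58 (SE 0.232, adjusted p = 2.09e-07), Slc34a3 by −2.49 (SE 0.474, adjusted p = 0.00493) and Kcne1l by −2.49 (SE 0.569, adjusted p = 0.0219). The split was 149 and 289 without background correction, 135 and 139 with scanner-processed intensities, 176 and 207 with Cy5 alone and 139 and 197 with the series matrix. The slide block called 240 genes, 141 of them among the 337, and ended the calls of Sprr2f (3.66, adjusted p = 0.09), Cyp2j13 (3.05, adjusted p = 0.0756), Slc34a3 (−2.47, adjusted p = 0.0615) and Kcne1l (−2.42, adjusted p = 0.138), and the scan block, with 449 genes and 245 of the 337, that of Kcne1l (−2.30, adjusted p = 0.0667). The count was 112 without KO replicate 17 and 129 with the adipocyte covariate, and without WT replicate 12 the split was 50 and 164. The F test of the interaction called 106 genes, and 198 and 475 with slide and scan day as blocks, 74 and 102 of them among the 106. Without KO replicate 17 it called 41, and without WT replicate 18 it called 265.

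Changes between days 1 and 7 in WT kidneys gave the background against which the genotypes were compared. Eya1, a regulator of nephron progenitors, fell by 4.39 (SE 0.487, adjusted p = 1.65e-06), the Wnt inhibitor Dkk1 by 3.83 (adjusted p = 2.24e-06), and the Notch target Hes5 by 3.21 (adjusted p = 8.41e-06). Sox11 fell by 3.13 (adjusted p = 1.35e-07), Bmper by 3.13 (adjusted p = 7.20e-07) and Amph by 3.05 (adjusted p = 5.48e-07). Elavl4 fell by 3.79 (adjusted p = 2.24e-06, above background on 3 of 4 arrays of day 7) and Sprr2f by 3.05 (adjusted p = 0.00707). The sulphate carrier Slc13a1 rose by 3.52 (adjusted p = 1.17e-05), the thyroid hormone deiodinase Dio1 by 3.25 (adjusted p = 5.62e-06), Fndc1 by 3.03 (adjusted p = 0.00321) and Glod5 by 2.93 (adjusted p = 3.59e-06). The kallikreins Klk1b4 (3.86, SE 0.509, adjusted p = 1.26e-05), Klk1b8 (3.44, adjusted p = 9.17e-06) and Klk1b26 (3.33, adjusted p = 1.21e-04) rose, and since their sequences are close, which paralog was measured is uncertain. In all 3705 genes changed, 1994 higher and 1711 lower, with 1681 and 2442 in scanner-processed intensities, 197 and 474 with median centring, and 3818 in total with slide as a random block. Age and scan day were largely confounded: the third scan day held 3 of the 4 arrays of day 1 and 1 of the 4 arrays of day 7. With slide and scan day as fixed blocks 2630 and 3820 genes passed, 2011 and 2641 of them among the 3705, and the slide block ended the call of Sprr2f (−3.17, adjusted p = 0.0602). Within the third scan day 1095 genes passed, 745 of them among the 3705.

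Of the 35 lists, 19 passed in WT between days 1 and 7, and none passed with an estimated correlation, where adjusted p ran from 0.231 to 0.451. Cell cycle genes had a mean of −1.14 (adjusted p = 1.56e-17), with 19 lower, such as Top2a (−1.61), Cdk1 (−1.25) and Pcna (−1.24). Nephron progenitors had a mean of −1.25 (adjusted p = 3.88e-06), with 6 of 12 lower, among them Uncx (−2.42), Gdnf (−1.03) and Six2, which was not well above background on any array of day 7 and at least 6.04-fold lower there. The early nephron and ureteric tip had a mean of −0.86 (adjusted p = 7.89e-05), with Fgf8 (−2.68), Etv4 (−2.66) and Lhx1 (−1.76) lower, and hedgehog, BMP and Wnt signalling −0.30 (adjusted p = 0.0492). Lists that passed as higher were the proximal tubule (mean 1.20, adjusted p = 1.77e-10, 13 of 29 members higher), intercalated cells (1.01, adjusted p = 3.88e-06, with Slc26a4 1.91) and the thick ascending limb (0.87, adjusted p = 8.02e-05, with Egf 2.33). Higher too were oxidative phosphorylation (0.40, adjusted p = 3.27e-06), fatty acid oxidation (0.54), the distal convoluted tubule (0.74, with Slc12a3 1.89 and Klk1 2.16), collecting duct principal cells (0.68) and osmotic response (0.73). Macrophages (0.58), immediate early genes (0.48), endothelium (0.57), chemokines (0.45), hypoxia (0.38), adipocytes (1.04, with Ucp1 2.35) and tubular injury (0.39) also passed as higher, the last with Spp1 (2.14) and Cryab (2.08) up and Sox9 (−2.79) down. The fit with slide as a fixed block called 18 lists, with scan day 14, and within the third scan day 10. Both blocks ended the calls of the distal convoluted tubule (adjusted p = 0.134 and 0.139), hypoxia (adjusted p = 0.195 and 0.0986) and hedgehog, BMP and Wnt signalling (adjusted p = 0.222 and 0.139). Scan day also ended those of collecting duct principal cells (adjusted p = 0.146), tubular injury (adjusted p = 0.0986), endothelium (adjusted p = 0.0783) and adipocytes (adjusted p = 0.139). Both called extracellular matrix and fibrosis higher (adjusted p = 0.00519 and 0.00731, and adjusted p = 0.419 and 0.520 with an estimated correlation) and skeletal muscle lower (adjusted p = 0.0149 and 0.0121, and adjusted p = 0.504 and 0.520 with an estimated correlation).

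Between days 1 and 14 in WT, 5706 genes changed, 2900 higher and 2806 lower. The highest were the fat genes Cfd (6.11, SE 1.36, adjusted p = 0.00141, above background on 1 of 4 arrays of day 1), Cidea (5.26, adjusted p = 6.63e-04), Cox8b (5.12, adjusted p = 3.47e-04) and Ucp1 (5.10, adjusted p = 8.81e-05), with Dnase1 (5.18, adjusted p = 7.18e-08). The lowest were Nts (−4.65, adjusted p = 2.63e-06), the Wnt agonist Rspo1 (−4.55, adjusted p = 8.25e-06), Eya1 (−4.48, adjusted p = 4.24e-06), Sox11 (−4.44, adjusted p = 4.49e-09) and Dkk1 (−4.35, adjusted p = 1.29e-06). Rspo1 and Dkk1 were above background on 1 of 2 arrays of day 14. The split was 448 and 3040 with median centring. The median difference of all genes was −0.40 there, 0.135 with Cy5 alone and 0.00283 with loess. In a fit with slide as a random block 4351 genes passed, with scan day as a fixed block 5087 (3453 of them among the 5706), where Cfd was 9.89 (adjusted p = 6.82e-04), Cidea 7.43, Cox8b 6.86 and Dnase1 6.68, and without WT replicate 17 the count was 3248. The slide of day 14 held no other age, so slide and age cannot be told apart there. Scan day as a block rests in this comparison on the KO arrays of day 7 alone. KO replicates 15 and 16 lay on the first scan day, with day 14, and KO replicates 13 and 14 on the third. The adipocyte list was high in KO replicate 13 (2.56), so the blocked values are no check of the fat genes.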

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

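Of the tests in this part, those on KO replicate 12, the one on fat tissue and those on slide and sex for day 7 were chosen only after the result was seen.

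The genotype effect depended on age for 106 genes by the F test, and differed between late and early ages for 337 genes by its own contrast. Both tests draw on day 14, where genotype and sex cannot be told apart and fat markers were high in WT. Neither was run with Xist as a covariate. The 10 genes named for the contrast were Sprr2f (3.86), Sox9 (2.84), Cyp2j13 (2.78), Krt20 (2.52), Anxa13 (2.05), Egf (−3.26), Dnase1 (−3.15), Kcnt1 (−2.58), Slc34a3 (−2.49) and Kcne1l (−2.49), as log2 differences of late minus early. Of 100 exchanges of genotype labels within ages, 4 gave as many interaction genes and 3 as many late against early genes, the real assignment included. Both shares lie under 0.05, without adjustment over the tests of chance in this part. The exchanges were drawn at random and took no account of slide, so for these counts chance is not firmly excluded. The highest other values, 644 and 578, exceeded the real ones, which points to a structure of the samples that some exchanges follow. With slide as a block the real counts were 198 and 240, of which 74 and 141 genes were shared with the unblocked calls.

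For KO against WT over all ages, 1 of 100 exchanges, the real one, reached 1544 genes, and the highest other called 42, so chance can be excluded. For the 16 gene lists over all ages chance cannot be excluded, since 6 of 100 exchanges gave as many and the highest other gave 20. For the 65 list tests by age the share was 2 of 100, under 0.05 without adjustment over these tests, and another exchange also gave 65. On day 1 the real split of 8 arrays was 1 of 35, with 59 genes against at most 8 elsewhere, so chance can be excluded at 0.05 without such adjustment. WT day 7 against WT day 1 was also 1 of 35, with 3705 genes against at most 2928 and 19 lists against at most 17. The split with 2928 genes put the 4 arrays of the third scan day on 1 side, and age and scan day are largely confounded here. With scan day as a block 3820 genes passed, 2641 of them among the 3705, and within that scan day 1095. On day 2 chance cannot be excluded: 42 of 100 splits gave as many as the 1052 genes at an unadjusted p under 0.05. The highest other split there, with 4854 genes, put KO replicates 6, 7 and 8 and WT replicates 6 and 8, all from the second scan day, on 1 side, and WT replicate 7 of that scan on the other, which points to a structure of the samples. With scan day as a block, 0 genes passed on day 2 in limma (1908 at an unadjusted p under 0.05).

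Single arrays stood apart from their group in 10 of the 111 groups tested, where chance gives 5.55. Pmaip1 was −1.14 in KO replicate 2 of day 1 (mean of the others 0.567) and −1.42 in WT replicate 4 (others −2.1). Krt19 was −0.95 in WT replicate 4 of day 1 (others −1.06). Abca13 was 1.36 in WT replicate 2 of day 1 (others 2.51). Dio1 was 4.58 in WT replicate 16 of day 7 (others 3.8). Ppp3ca was 0.15 in WT replicate 13 of day 7 (others −0.496). Ppp3cc was −1.30 in WT replicate 2 of day 1 (others −0.792) and −0.55 in KO replicate 14 of day 7 (others −0.965). Ppp3r1 was −0.40 in KO replicate 10 of day 2 (others −0.977). The SD of log2 ratios over genes was 0.699 in WT replicate 7 of day 2, where the others averaged 1.14.

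The lower oxidative phosphorylation RNA in KO can be set against other tissue, sex and slides. Fat attached to the WT kidneys of day 14 would lower the list only there, but it differed by −0.302 (SE 0.0531) over days 1, 2, 3 and 7, where the adipocyte list differed by 0.0973 (SE 0.233). Brown fat on days 3 and 7 is not covered by this test. The brown fat gene Ucp1 reached 4.21 in WT replicate 11 and 1.89 in KO replicate 11 of day 3. On day 7 it reached 5.04 in WT replicate 15 and 3.24 in KO replicate 13. With Xist as a covariate the difference was −0.352 (SE 0.0651) against −0.367 without, which argues against sex as the whole cause. Inside slides it was −0.263 (SE 0.0913) and below 0 in 10 of 10 comparisons, which argues against slide or scan day. The list p rests on 27 members (adjusted p = 5.77e-21 preset, 0.0517 with an estimated correlation), so a lower share of respiratory chain RNA in KO is a hypothesis. On day 14 sex and fat stay open, and on days 3 and 7 brown fat does.

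The day 7 genes can be set against slide, sex and chance, and chance cannot be excluded: 3 of 35 splits gave as many as the real 867. The highest other, 2251 genes, put KO replicates 13, 14 and 15 with WT replicate 13, and a further split with 994 put KO replicates 13, 14 and 16 with it. Both kept the 3 arrays of the shared slide on 1 side, which points to that slide or its scan day as a structure of the samples. On day 7 the third scan day held the same 3 arrays, so slide and scan day cannot be told apart there. With slide as a block 299 genes passed, 163 of them among the 867. The median ratio of the blocked to the unblocked difference over the 867 was 0.975 (0.827 to 1.09 without each day 7 array in turn). It does not decide on slide, because the 867 were called from these same arrays. KO replicates 15 and 16 shared their slide only with the day 0 arrays, and WT replicate 16 was alone on its slide. The blocked difference does not rest on these arrays, and the ratio was 0.975 without each of them. For the 704 genes whose call the block ended, the median difference went from 0.727 (median SE 0.175) to 0.644 (median SE 0.246). These calls ended with a larger SE and a somewhat smaller difference. Slide as a part or the whole of the day 7 difference stays open. From the other day 7 arrays alone, 443 genes were called, with a median size of 0.915 there. On the shared slide their median difference in that direction was 0.404, and 82.4% kept their sign. Pairs of arrays of 1 genotype, age and slide gave 50.6% to 64.5%. The value on the shared slide rests on WT replicate 13 alone, so it decides nothing. With Xist as a covariate 715 of the 867 genes still passed and each kept at least 50% of its difference, while the sex-linked Ddx3y went from 1.57 to 0.17, which argues against sex as the whole cause.

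KO replicate 12, of day 3, was flagged as close to the WT arrays. Its correlation with WT replicate 12, on the same slide, was 0.986, the highest of any pair of arrays. The mean correlation with the WT arrays of day 3 was 0.977 for KO replicate 12 and 0.976 for KO replicate 11. Correlation therefore does not set KO replicate 12 apart. Its Sprr2f was 1.21 and its Slc12a3 2.18, against 5.62 and 0.27 in KO replicate 11, the other KO array of that day. An exchange with a WT array of day 3 would leave a WT array among the KO scores, but the highest WT genotype score there was −0.0747, below the lowest of the other KO arrays, −0.0169. Poor hybridisation is argued against by its correlation of 0.976 with the other arrays of its day. Its score of 0.0491 lies above those of 17 of the 18 WT arrays (at most 0.00964), below the 0.0839 of WT replicate 7, whose log2 ratios had the smallest SD, and above those of 4 KO arrays, so a WT or non-recombined animal under a KO label cannot be told apart from a weak genotype effect in that animal, because the score ranges of the genotypes overlap, also without WT replicate 7, whose place alone puts the score inside the WT range.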

How the results depend on the processing

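These alternatives were chosen only after the data were seen: fixed blocks and the third scan day alone for the WT ages, leaving out KO replicate 15 and WT replicate 17, leaving out these and WT replicate 7, the adipocyte covariate, Xist as a covariate on day 7, an estimated correlation under blocks, and leaving out days 0 and 14. Of 4972 values of named genes under alternatives, 4723 kept their side of the threshold and direction, 248 lost the call and 1 turned. Of 13685 list values 13063 counted as kept, 181 gained the call, 25 turned and the others lost it. A list that passed in neither fit counted as kept whatever its direction, so turns of such lists are not among the 25. Of 803 counts 690 stayed within 1.5 times the reported one. These totals include leaving out each array in turn. For single ages and the WT ages, an array outside the comparison leaves the difference itself unchanged and moves only its SE. The shares kept are therefore in part fixed by the design and are no measure of robustness. Cidea and Cox8b on day 14 and Mep1b on day 1 lost their calls most often. Signal over background limits what the dimmest genes can show, since a difference involving a group with no array above background is only a bound, and 5 arrays or fewer per group limit the single ages. Aquantile moves no log ratio and is left out of these totals. The cause of each shift below was not tested, except that fewer arrays or fewer lists enter where the wording says so.

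Counts of genes KO against WT moved as follows. With Cy5 alone, day 0 gave 60, day 1 204, day 14 1670 and the interaction 160, and Ppp3r1 turned to 0.15 (adjusted p = 0.841). With the adipocyte covariate, day 1 gave 35, day 14 433, late against early 129 and the interaction 47. With ages weighted equally, all ages gave 1004. With array quality weights, all ages gave 2887, day 0 129, day 1 2398, day 7 1927, late against early 680, the interaction 580 and WT day 7 against day 1 11190. Fits on 1 age gave 21 on day 1 and 140 on day 7. The mean over probes gave 39 on day 1 and −0.45 for Ppp3r1, past the threshold, and its other probes gave −0.44 and −0.76. Median centring gave 155 over all ages, 0 on day 0 (219 at an unadjusted p under 0.05, limma), 1 on day 1, 130 on day 7, 75 on day 14, 16 for late against early, 10 for the interaction, 671 and 3488 for WT day 7 and day 14 against day 1, and −0.378 for the maturation relation of day 7. Without background correction, day 0 gave 47, day 1 230 and the interaction 237, and without the filter day 1 gave 32. Scanner-processed intensities gave 91 on day 0 and 112 on day 1, and the series matrix 128 and 174. Days 1, 2 and 7 alone gave 639 over all ages, and leaving out days 0 and 14 gave 866. Leaving out KO replicate 15 and WT replicate 17 gave 951 over all ages, 323 on day 14 and 3297 for WT day 14 against day 1, and with WT replicate 7 left out too, 32 on day 0, 196 on day 1 and 538 on day 14. With an estimated correlation the lists called were 1 over all ages, 3 by age and 0 in WT (19 with the preset one).

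With slide as a fixed block, day 0 gave 48, day 1 22, day 7 299, day 14 1690 and the interaction 198; as a random block, day 0 gave 57, day 1 130, day 14 1671, late against early 525 and the interaction 269. With scan day fixed, day 0 gave 72, day 14 1959 and the interaction 475, and as a random block 56, 1722 and 255, with 113 on day 1. Neither fixed block can change a difference of day 0 or of day 14, since the arrays of each shared a slide and a scan day. Single scan days gave 0, 1 and 13 over all ages, and the third 1095 genes and 10 lists for WT day 7 against day 1, from fewer arrays. With the replicate number as a block, all ages gave 1797, day 0 5, day 1 18, day 7 1333 and the interaction 60. The numbers were not taken as pairs, because the labels tie them to no litter. Nor did every pair have a correlation of deviations over 0.1. Of 17 pairs with a correlation 13 exceeded 0.1, with a range from −0.389 to 0.696. Of all 18 pairs, 13 shared a slide. In 10 of the 17 the KO array correlated best with the WT array of its own number.

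Among lists that passed in the reported fit or under the alternative, directions turned for these, given as adjusted p. Turns of lists that passed in neither are not given. On day 2, the thick ascending limb: no background correction 0.006, scanner-processed 0.00166, Cy5 alone 0.000166, series matrix 0.00185. Endothelium of day 2: 0.78, 0.357, 0.495 and 0.36 in the same order, and array weights 0.838. Nephron progenitors of day 2: Cy5 alone 0.0485, without WT replicate 7 0.00119, and without it and the other 2 arrays 0.00223. Median centring turned cell cycle on day 2 (0.897) and renal stroma on day 14 (0.998). The adipocyte covariate turned the adipocyte list by its construction (0.839 on day 2, 0.923 on day 14). Within single scan days these turned: cell cycle (0.425) in the first, endothelium (0.47) in the second, and podocytes (0.0291), renal stroma (0.0169), extracellular matrix and fibrosis (0.523) and liver (0.604) in the third, with Gsdmc at −0.031 on the log2 scale in the first. On day 3, macrophages turned without KO replicate 11 (0.812), and adipocytes without KO replicate 11 (0.00245) or WT replicate 12 (5.43e-06). Over all single arrays left out, adjusted p ran from 2.41e-06 to 0.812 for macrophages of day 3, from 1.63e-07 to 0.994 for adipocytes of day 3 and from 0.00119 to 0.996 for nephron progenitors of day 2. The maturation relation of day 2 turned without KO replicate 9 (0.00538) or WT replicate 8 (0.0334).

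Leaving out 1 array at a time gave 1187 to 1891 genes over all ages, 14 to 50 on day 0, 7 to 270 on day 1, 0 to 1 on days 2 and 3, 374 to 1548 on day 7, 2.4e+02 to 1370 on day 14, 112 to 456 for late against early, 41 to 265 for the interaction, 2617 to 4194 for WT day 7 and 3248 to 6272 for WT day 14 against day 1. Lists called ran from 14 to 16 over all ages, 56 to 69 by age and 16 to 20 in WT, Ppp3r1 from −0.19 to −0.06, and the maturation relations from −0.227 to 0.0334 and from −0.278 to −0.16. Arrays that moved a count over 1.5 times were, on day 0, KO replicate 4 (50) and WT replicate 7 (31). On day 1 they were KO replicates 2 (270), 3 (7), 4 (10), 5 (11), 6 (32) and 14 (93) and WT replicates 3 (8), 4 (10), 5 (10), 7 (163), 9 (38), 11 (32), 12 (32), 14 (31), 15 (31) and 16 (37). On days 2 and 3 WT replicates 10 and 11 gave 1 gene each. On day 7 they were KO replicate 14 (436) and WT replicates 13 (1548), 14 (374), 15 (405) and 16 (393), and on day 14 KO replicate 17 (92 higher and 149 lower) and WT replicate 17 (310). For late against early they were KO replicate 17 (112) and WT replicate 12 (50 higher and 164 lower), for the interaction KO replicate 17 (41) and WT replicates 7 (184) and 18 (265), and for WT day 14 against day 1 WT replicate 17 (3248).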

Other observations

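The tests of the maturation relation in this part were planned, and the single arrays with high markers of other tissue were picked out after their values were seen.

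Marker lists of neighbouring tissue were high on single arrays. Adrenal markers, of steroid hormone synthesis, averaged 2.47 in KO replicate 3 of day 1, with Star, which carries cholesterol into mitochondria, at 4.97. The other KO arrays of day 1 lay between 0.631 and 0.782 for the list and the WT arrays between 0.521 and 0.702. Skeletal muscle markers averaged 1.77 in KO replicate 5 and 1.11 in WT replicate 4, both of day 1, and no other array exceeded 0.0548. Liver markers averaged 1.75 and 1.71 in WT replicates 6 and 8 of day 2, against 0.232 to 0.377 in the other WT arrays of that day.

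Fat markers were high on several arrays at 3 and more days of age. The adipocyte list averaged 3.19 in WT replicate 11 and 2.70 in KO replicate 11 (day 3), 2.56 in KO replicate 13 and 2.81 in WT replicate 15 (day 7), and 2.84 and 3.00 in the WT arrays of day 14. Ucp1, the uncoupling protein of brown fat, was 5.22 and 5.37 on the latter and 0.753 and 0.013 on the KO arrays of day 14, 4.21 in WT replicate 11, 5.04 in WT replicate 15 and 3.24 in KO replicate 13.

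A hypothesis was that genes which rise with age in WT kidneys may be lower in KO. Across 22938 genes, which are not independent replicates, the KO minus WT difference on day 2 had a Spearman correlation of −0.107 with WT day 7 minus day 1 (exact p = 0.746 over 252 relabellings, smallest possible 0.00794) and a Pearson correlation of −0.0878 (exact p = 0.762). The difference on day 7 had −0.215 with WT day 14 minus day 1 (exact p = 0.371 over 70 relabellings, smallest possible 0.0286) and a Pearson correlation of −0.248 (exact p = 0.229). Adjusted over the 2 relations the Spearman p-values were 0.746 and 0.742. The bound set beforehand, an exact p of 0.05 or more, was meant to exclude the hypothesis; that was wrong, because a p that misses the threshold does not exclude a relation, so the tests leave it open.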
